A study of Arabidopsis thaliana with 15 samples.

How the data were processed

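Expression was measured in whole germinated seeds of Arabidopsis thaliana, accession Columbia, on 15 Affymetrix arrays. Per the labels, seeds were stratified at 4 °C for 72 h, germinated at 22 °C in constant light, picked at radicle protrusion and incubated in 10 µM ABA at 20 °C in darkness for 0, 2, 12, 24 or 72 h. Each of the 5 times had 3 biological replicates, each a pool of seeds harvested in bulk from several plants. Labelled cDNA was made from 50 ng of total RNA with the NuGEN Ovation PicoSL kit. The deposited values are log2 expression values that the authors made with RMA, which corrects background, normalizes quantiles and summarizes probe sets. The RMA version, the array design, the definition of the probe sets and the genome build are not given in the sources used here. The deposited matrix held 35986 probe sets with values from 1.49 to 12.8 on the log2 scale. Array quartiles still differed between arrays, with an interquartile range of 2.89 on 2 h replicate 2 against 3.73 to 4.12 elsewhere. No array was removed. The number of arrays per time limits the precision.

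Probe set names carry an Arabidopsis locus. Where several probe sets named 1 locus, as for 5838 loci, the one with the highest mean over all arrays was kept, which left 27981 loci. A reference gene table supplied symbols for names only. It held 27241 of the loci, and 740 were not found, 261 of them organelle loci. In 195 cases a locus had values identical to those of another locus, and such loci were tested but not named.

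Differences between times were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes) in 1 fit of all 15 arrays with 1 mean per time and no further term. Tests were two-sided, p-values were adjusted by the method of Benjamini and Hochberg over all 27981 loci, and a gene was called at adjusted p under 0.05. The comparisons were each later time against 0 h, each step between successive times and a moderated F test over the 4 differences from 0 h. For genes called by the F test whose time means spanned at least 1, the time of the highest mean was counted.

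Gene lists were tested with camera in limma with a preset inter-gene correlation of 0.01, adjusted over the 25 lists of a comparison. The lists held LEA proteins, seed storage and oil body proteins, ABA receptors, clade A PP2C phosphatases, ABA response markers, seed maturation and ABA transcription factors, ABA synthesis and catabolism, gibberellin genes, sucrose and raffinose family synthesis, small heat shock proteins, antioxidants, cell cycle, expansins and xyloglucan transferases, root hairs, photosynthesis, dark and starvation response, clock, lipid mobilisation, seed oil synthesis, ribosomal proteins, endosperm and seed coat, root meristem, xylem, and the genes of the plastid and mitochondrial genomes. They named 466 loci, of which 465 were measured, and 2 loci stood in more than 1 list. Members called were also counted with p-values adjusted over the list alone. The comparisons, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. A further 7 lists were written after the largest changes had been seen and are used only in the closing section.

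The rule for named genes took, for each time against 0 h, the 8 largest rises and the 8 largest falls among called loci with 3 of 3 arrays beyond all 3 arrays of the other time, and for each step the 5 largest in either direction by the same criteria. It added up to 4 called members of each list at each time against 0 h, every PP2C and every dark- and starvation-induced gene at 72 h, the genes ABI3, ABI5, RD29B, EM1, EM6 and RAB18 at every time, and the 4 genes called in opposite directions at 2 times with the largest difference between them. Some of the genes so taken were left out of the text for length or because their call was lost without a single array.

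Alternatives were a term for the replicate number, repeated quantile normalization, centring of each array on its median, leaving out the 25% of genes with the lowest mean, an intensity trend in the variance prior, array quality weights, every probe set in place of 1 per locus, adjusted p under 0.01, leaving out each array in turn, fits of only the 6 arrays compared, a range of at least 2 for the time of highest expression, an estimated inter-gene correlation, and fry in place of camera. An estimated correlation with 2 h replicate 2 left out was added after that array had been seen to stand apart. Leaving out an array leaves 2 in its time, which are assumed to vary like the other times.

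In simulated data of this size genes were independent and few changed, unlike here. For 72 h against 0 h limma called 45% of 100 genes changed by 1 (log2) and 93% of 100 changed by 2. It called 7 unchanged genes and only the list shifted by 1. Real rates may differ.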

Results

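Whole Arabidopsis thaliana seeds of accession Columbia that had just germinated, with the radicle through the seed coat, were placed in 10 µM abscisic acid (ABA), the hormone of seed maturation and drought responses. They were held there in darkness at 20 °C and collected at 0, 2, 12, 24 and 72 h. Each time had 3 arrays, each from its own pool of seeds, 15 in all. Affymetrix arrays gave a log2 signal for 35986 probe sets, of which 1 was kept for each of 27981 loci. By the title of the series the course follows the return of tolerance of drying under ABA in germinated seeds, and no value used here measures that tolerance. The 0 h seeds, taken before incubation, are the background of every comparison with that time. Incubated seeds without ABA were not analysed here, so a difference from 0 h holds ABA, elapsed time, darkness and the move to another temperature together. Gene p-values measure the spread between pools, list p-values that between genes. Values after ± are standard errors of the fitted difference (n = 3 per time).

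One array stood apart. The 2 h replicate 2 array correlated across genes with the other two 2 h arrays at r of 0.889 and 0.901, while replicates of 1 time elsewhere, 2 h replicates 1 and 3 included, correlated at 0.986 to 0.995. Its interquartile range was 2.89 against 3.73 to 4.12 elsewhere. Values below include this array, and calls and list counts that change much without it stand beside them. The fit assumes equal spread at all times, not seen at 2 h. Centring each array on its median moved the median of all genes by 0.12 at 2 h against 0 h and by -0.17 from 2 h to 12 h, so changes in these comparisons stand relative to those shifts.

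**Figure D1:**
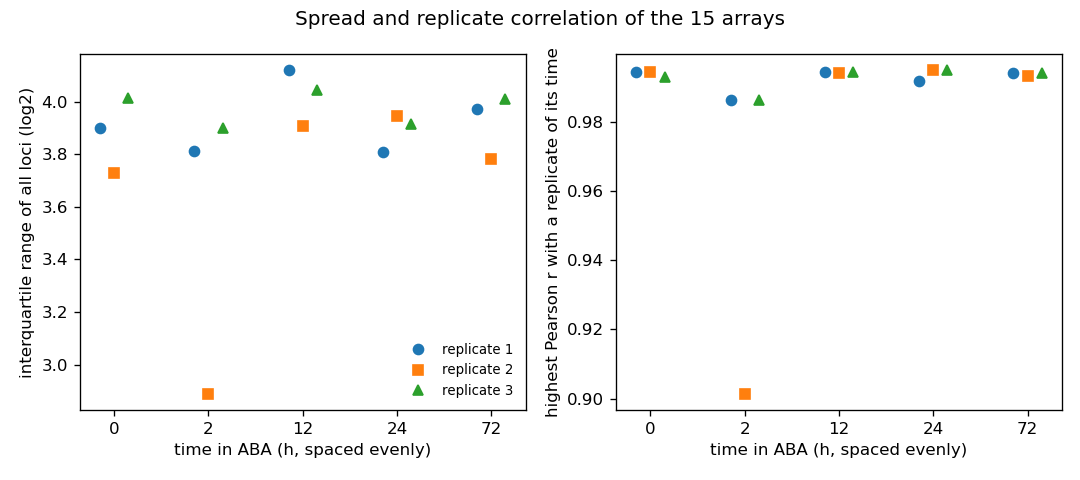
Interquartile range of all loci (log2, left) and highest Pearson correlation with another array of its own time (right) for each of the 15 arrays, by time in ABA, with 1 symbol per replicate. The 2 h replicate 2 array has a range of 2.89 and a highest correlation of 0.901, below all the others.

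Over the whole course, 12302 of 27981 genes (44.0%) changed at 1 or more times by the moderated F test in limma. Among them, 7247 had time means that spanned at least 1 on the log2 scale. Of these 7247 genes, 3187 (44.0%) were highest in the germinated seeds at 0 h and 1940 (26.8%) were highest at 72 h. Fewer were highest at 2 h (517, 7.13%), 12 h (555, 7.66%) or 24 h (1048, 14.5%). The number highest at 2 h was 845 without 2 h replicate 1, 806 without 2 h replicate 2 and 1020 without 2 h replicate 3.

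**Figure D2:**
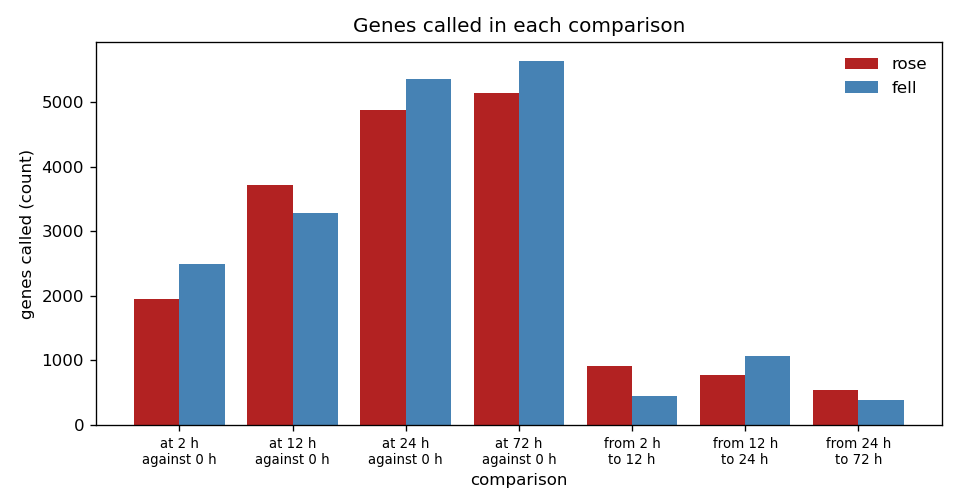
Number of genes called as higher (rose) or lower (fell) at adjusted p under 0.05 in each comparison of 3 arrays with 3 arrays. Bars reach 5137 rises and 5640 falls at 72 h against 0 h and 540 rises and 388 falls from 24 h to 72 h.

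The 2 h seeds against 0 h show what changed first. Of 51 genes for late embryogenesis abundant (LEA) proteins, which protect drying embryos, 29 rose within 2 h, as did 15 of 24 ABA response markers. RD29B, a classic ABA-induced gene, rose by 7.16 ± 0.20 (log2, adjusted p = 1.15e-11), from 3.08 to 10.24. Signals were not tested against background, and RD29B at 0 h lay near the lower quartile of all loci. Changes from or to such dim levels are bounds, and no folds are given. The LEA genes EM1 and EM6 rose by 6.33 ± 0.20 and 5.15 ± 0.27. ABI5, the transcription factor acting on them, rose by 4.33 ± 0.14 and ABI3, a master regulator of seed maturation, by 1.47 ± 0.21 (adjusted p = 2.07e-04). The dehydrin gene RAB18 rose by 4.51 ± 0.35. Replicate 2 of 2 h was lowest for ABI3 (8.1 against 9.0 and 9.1) but highest for RAB18. RD29B led the 8 largest rises, before AT2G38905 (7.15 ± 0.23), AT4G36600 (7.15 ± 0.19), AT2G25890 (6.98 ± 0.19), AT1G02700 (6.96 ± 0.13), AT2G18540 (6.95 ± 0.20), AT3G15280 (6.82 ± 0.17) and AT5G07330 (6.72 ± 0.21). The 8 largest falls were AT2G43140 (-5.24 ± 0.23, adjusted p = 1.39e-09), AT2G27420 (-4.93 ± 0.21), the ABA receptor gene PYL6 (-4.51 ± 0.20), OCT3 (-4.36 ± 0.32), ZF1 (-4.02 ± 0.18), AT5G48430 (-4.02), the deadenylase gene CAF1a (-3.98 ± 0.18) and NAC048 (-3.97 ± 0.24). Each had 3 of 3 arrays beyond all 3 of the other time.

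**Figure D3:**
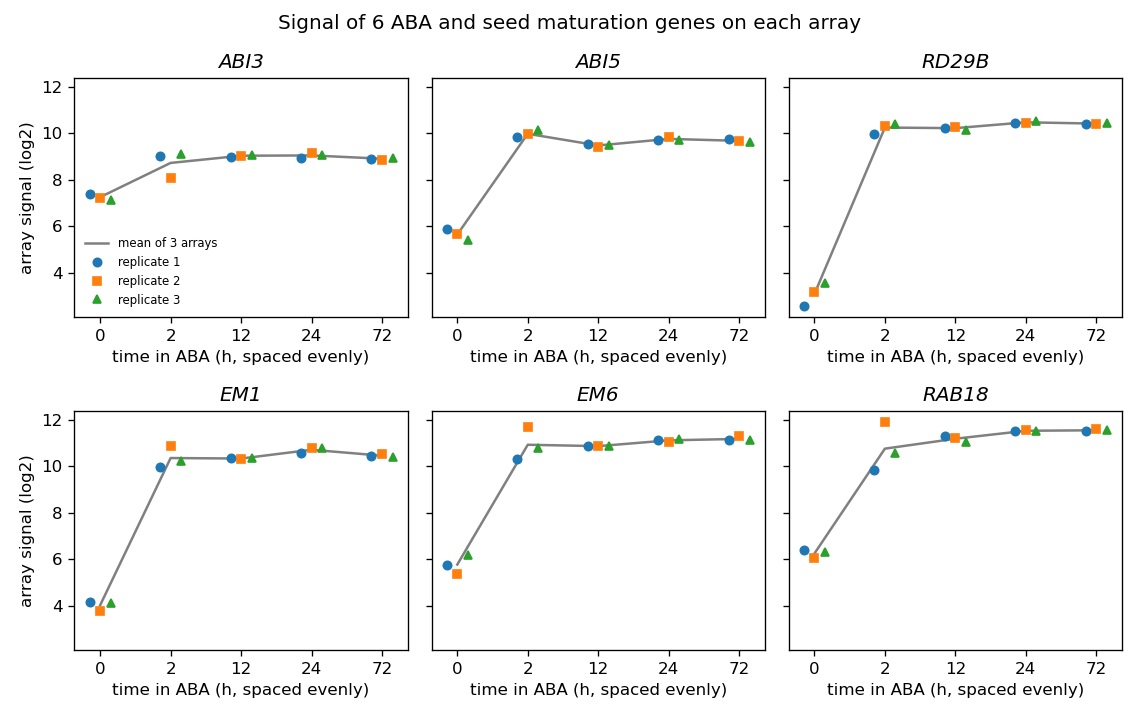
Array signal (log2) of ABI3, ABI5, RD29B, EM1, EM6 and RAB18 on each array by time in ABA, with 1 symbol per replicate and a line through the mean of 3 arrays. The mean of RD29B is 3.08 at 0 h, 10.24 at 2 h and 10.47 at 24 h.

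Of the 51 LEA genes, 29 rose and 2 fell at 2 h, or 34 and 3 adjusted over the list alone (median 2.63, adjusted p = 1.47e-26 by camera, the set test in limma). AT1G72100 rose by 6.71 ± 0.17, AT2G42560 by 6.57 ± 0.35 and AT4G39130 by 6.53 ± 0.28. Seed storage and oil body genes rose as well, 11 of 19 with no fall, or 13 adjusted over the list alone (median 2.73, adjusted p = 2.48e-11, but adjusted p = 0.204 with an estimated correlation). Among them the oleosin genes OLEO2 and OLEO5, for the coat proteins of oil bodies, rose by 5.81 ± 0.34 and 4.55 ± 0.38, and the storage protein gene AT2G28490 by 5.24 ± 0.48. The storage median was 1.48 without 2 h replicate 2. In sucrose and raffinose family synthesis 7 of 16 genes rose and 2 fell, or 8 and 2 adjusted over the list alone (median 0.39, adjusted p = 0.00439, and adjusted p = 0.0871 with an estimated correlation). SUS3, a sucrose synthase gene, rose by 4.27 ± 0.28 and GOLS2, which makes the precursor of raffinose, by 3.82 ± 0.45, whereas DIN10, a raffinose synthase gene, fell (-3.18 ± 0.19).

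The ABA pathway moved in opposite directions at its receptors and at the phosphatases they inhibit. Of 14 ABA receptor genes, 8 fell and 2 rose, also when adjusted over the list alone (median -1.09, adjusted p = 7.06e-04). Beside PYL6, PYL4 fell (-2.35 ± 0.25), as did PYL1 (-2.22 ± 0.17) and PYL5 (-1.98 ± 0.24). Of the 9 clade A PP2C genes, negative regulators of ABA signalling, 8 rose and 1 fell, with 8 and 1 adjusted over the list alone (median 2.06, adjusted p = 3.46e-07, and adjusted p = 0.0543 with an estimated correlation). AHG1 rose by 5.81 ± 0.22, HAI3 by 3.54 ± 0.22, HAI2 by 3.48 ± 0.31 and HAI1 by 2.09 ± 0.20. ABA response markers rose in 15 of 24 cases with no fall, or 18 adjusted over the list alone (median 1.33, adjusted p = 2.52e-11), among them RD29A (6.34 ± 0.36), HVA22B (5.73 ± 0.20) and AFP1 (4.09 ± 0.35). Seed maturation and ABA transcription factors rose in 5 of 20 cases with no fall, or 6 rises and 1 fall adjusted over the list alone (median 0.42, adjusted p = 0.00148, median 0.16 without 2 h replicate 2, and adjusted p = 0.0583 with an estimated correlation and that array left out together). EEL, a bZIP gene of late seed maturation, rose by 2.40 ± 0.22. In ABA synthesis and catabolism 5 of 17 rose, or 7 rises and 1 fall adjusted over the list alone (median 0.50, adjusted p = 0.0111, and adjusted p = 0.0871 with an estimated correlation). Here ABA1, for a step of ABA synthesis, rose by 1.72 ± 0.23 and CYP707A2, for ABA breakdown, by 1.68 ± 0.21. This list was not called without 2 h replicate 3 (adjusted p = 0.0818).

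Of 29 expansin and xyloglucan transferase genes, which loosen cell walls, 15 fell and 1 rose, also when adjusted over the list alone (median -0.99, adjusted p = 6.45e-07, but adjusted p = 0.0583 with an estimated correlation and 2 h replicate 2 left out together). EXPA17 fell (-3.09 ± 0.20), and so did XTH22 (-2.54 ± 0.25), EXPB1 (-2.28 ± 0.26) and EXPA10 (-2.02 ± 0.29). Nuclear photosynthesis genes fell in 25 of 41 cases with no rise, or 35 adjusted over the list alone (median -1.37, adjusted p = 7.27e-14, but adjusted p = 0.105 with an estimated correlation). The light-harvesting genes LHCB1.5 and LHCB1.2 changed by -2.33 ± 0.29 and -2.19 ± 0.48, and the list median was -0.80 without 2 h replicate 2. Root hair genes fell in 6 of 19 cases, also when adjusted over the list alone (median -0.34, adjusted p = 0.0015, but adjusted p = 0.354 with an estimated correlation), with RHD2, for the oxidase that drives hair growth, at -1.77 ± 0.21 and LRX1 at -1.43 ± 0.21. Their median was -0.65, with 10 falls, without 2 h replicate 2 and -0.13 without 2 h replicate 3. Xylem and secondary wall markers fell in 3 of 8 cases, also when adjusted over the list alone (median -0.30, adjusted p = 0.0376, but adjusted p = 0.317 with an estimated correlation). The cellulose synthase gene CESA4 changed by -1.36 ± 0.21 and the xylem protease gene XCP1 by -1.21 ± 0.24. The xylem call was lost without 2 h replicate 1 (adjusted p = 0.0935) or 2 h replicate 3 (adjusted p = 0.145), and the median was -0.48 without 2 h replicate 2.

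A further 3 lists were called at 2 h with few or no called members. Cell cycle genes had 1 fall among 35, and none adjusted over the list alone (median -0.29, adjusted p = 0.00152, but adjusted p = 0.354 with an estimated correlation). Without 2 h replicate 2 they had 2 rises and 3 falls, their median was -0.16 and the call was lost (adjusted p = 0.110). Endosperm and seed coat markers had 1 rise among 11, also adjusted over the list alone (median 0.40, adjusted p = 0.026, but adjusted p = 0.477 with an estimated correlation), which was MAN7, for a mannanase of seed cell walls (3.02 ± 0.18). That call was lost without 2 h replicate 2 (median 0.01, adjusted p = 0.367) and on repeating quantile normalization (median 0.19, adjusted p = 0.0532), and the median was 0.59 without 2 h replicate 3. Plastid genome genes had no call among 132, and none adjusted over the list alone (median -0.09, adjusted p = 0.00148, but adjusted p = 0.564 with an estimated correlation). Centring each array turned their median to 0.03 and ended the call (adjusted p = 0.102).

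The other 10 lists were not called at 2 h. Gibberellin genes had 8 rises and 3 falls among 25, or 9 and 3 adjusted over the list alone (adjusted p = 0.0723), with the growth repressor gene RGL2 up by 1.34 ± 0.14 and the receptor gene GID1B at -1.89 ± 0.38. The list was called without 0 h replicate 3 (adjusted p = 0.0486). Antioxidant and tocopherol genes had 4 rises and 1 fall among 22, or 4 and 2 adjusted over the list alone (adjusted p = 0.803). Their median (-0.13) and mean (0.25) differed in sign while camera pointed down, and the peroxiredoxin gene PER1 rose by 5.68 ± 0.36. Small heat shock protein genes had 2 falls among 17, or 1 rise and 2 falls adjusted over the list alone (adjusted p = 0.712), with HSP15.4 at -3.76 ± 0.27 and a list median of 0.84 that was -0.06 without 2 h replicate 2. Dark- and starvation-induced genes had 2 rises and 2 falls among 8, also adjusted over the list alone (adjusted p = 0.836). Clock genes had 1 rise and 1 fall among 15, also adjusted over the list alone (median -0.78, adjusted p = 0.0565). They were called without 0 h replicate 2 (adjusted p = 0.0243), without 2 h replicate 2 (1 rise and 6 falls, median -0.33, adjusted p = 0.00278) and with each array centred (adjusted p = 0.0437). Lipid mobilisation had 1 rise among 19, also adjusted over the list alone (adjusted p = 0.299), which was ACN1 (1.80 ± 0.18), and was called without 2 h replicate 3 (median -0.18, adjusted p = 0.0385). Seed oil synthesis had 1 rise and 2 falls among 12, or 1 and 3 adjusted over the list alone (adjusted p = 0.286). No call was made among 29 cytosolic ribosomal protein genes (adjusted p = 0.0503), 5 root meristem markers (adjusted p = 0.659) or 129 mitochondrial genome genes (adjusted p = 0.429), nor when adjusted over the list alone, while 2 mitochondrial genes rose without 2 h replicate 2. The ribosomal list was called without 0 h replicate 1 (adjusted p = 0.0472), 0 h replicate 3 (0.0490), 2 h replicate 3 (0.0224), 12 h replicate 2 (0.0499), 24 h replicate 1 (0.0470) or 24 h replicate 2 (0.0472). For root meristem markers the median (0.05) and the mean (-0.13) differed in sign.

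In all, limma called 4433 genes at 2 h at adjusted p under 0.05, 1946 up and 2487 down. By at least 1, 792 rose and 1438 fell. The count was 7086 without 2 h replicate 1 (3117 up, 1277 of them by at least 1, and 3969 down) and 6805 without 2 h replicate 3 (3621 up, 1210 of them by at least 1), and the rises were 1284 and 1294 without 0 h replicate 2 and 3. With each array centred 2352 rose and 2017 fell, so the larger direction depended on the scaling. The 2 h and 0 h arrays alone called 1276.

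By 12 h, the second comparison with 0 h, the question is which changes had spread or deepened. LEA genes were up in 31 of 51 cases, and photosynthesis genes were down in 37 of 41. The dehydrin gene AT4G39130 rose by 7.67 ± 0.28 (adjusted p = 1.66e-10), AT4G36600 by 7.34 ± 0.19, AT4G31830 by 7.22 ± 0.30 and RD29B by 7.13 ± 0.20. EM1 rose by 6.31 and EM6 by 5.09, RAB18 by 4.94, ABI5 by 3.83 ± 0.14 and ABI3 by 1.78 ± 0.21. ELIP1 and ELIP2, for early light-induced proteins of the chloroplast, changed by -7.51 ± 0.39 (adjusted p = 6.26e-09) and -7.19 ± 0.95. RBCS1B, for the Rubisco small subunit, changed by -5.53 (adjusted p = 9.28e-04), the chlorophyll synthesis gene GUN5 by -5.26 ± 0.66 and the calmodulin-like gene TCH3 by -5.05 ± 0.54.

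Of 51 LEA genes 31 rose and 3 fell at 12 h, or 31 and 4 adjusted over the list alone (median 2.61, adjusted p = 1.93e-21, but adjusted p = 0.0893 with an estimated correlation). Storage and oil body genes had 11 rises and no fall among 19, or 13 adjusted over the list alone (median 3.37, adjusted p = 5.74e-11, but adjusted p = 0.208 with an estimated correlation), with OLEO2 up by 6.89 ± 0.34, AT2G28490 by 6.35 and OLEO5 by 5.90. ABA receptor genes had 8 falls among 14, or 2 rises and 8 falls adjusted over the list alone (median -0.96, adjusted p = 2.88e-04). That call held with an estimated correlation (adjusted p = 0.0489) but not with that and 2 h replicate 2 left out together (adjusted p = 0.0580). PYL6 stood at -5.48 ± 0.20, PYL11 at -2.46 ± 0.41 and PYL2 at -2.18 ± 0.45. Among clade A PP2C genes 6 of 9 rose and 1 fell, or 7 and 1 adjusted over the list alone (median 1.19, adjusted p = 9.81e-06, but adjusted p = 0.12 with an estimated correlation). AHG1 rose by 6.01 ± 0.22, HAI2 by 4.43 ± 0.31 and HAI3 by 4.31 ± 0.22. ABA response markers had 12 rises and 2 falls among 24, or 12 and 5 adjusted over the list alone (median 0.83, adjusted p = 2.88e-04, but adjusted p = 0.124 with an estimated correlation). Seed maturation and ABA transcription factors had 7 rises and no fall among 20, also adjusted over the list alone (median 0.11, adjusted p = 0.00268, but adjusted p = 0.0673 with an estimated correlation). EEL rose by 3.79 ± 0.22 and FUS3, a further master regulator of seed maturation, by 1.75 ± 0.28. The median of that list was 0.19 without 12 h replicate 1 and 0.07 without 12 h replicate 3. In ABA synthesis and catabolism 6 of 17 rose, or 6 rises and 1 fall adjusted over the list alone (median 0.30, adjusted p = 0.0119, but adjusted p = 0.12 with an estimated correlation), with CYP707A2 up by 2.12 ± 0.21 and NCED9, for the step that limits ABA synthesis, by 1.96 ± 0.25. Without 2 h replicate 2, ABA response markers had 13 rises and 6 falls and receptor genes 2 rises and 8 falls.

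Photosynthesis genes fell in these 37 cases with no rise, or 38 adjusted over the list alone (median -2.10, adjusted p = 4.82e-19, but adjusted p = 0.114 with an estimated correlation). LHCB1.2 changed by -4.31 ± 0.48, PSAK of photosystem I by -3.82 ± 0.46 and LHCB5 by -3.48 ± 0.46. Expansin and xyloglucan transferase genes had 14 falls and 4 rises among 29, or 15 and 5 adjusted over the list alone (median -0.69, adjusted p = 0.00268, but adjusted p = 0.186 with an estimated correlation). Root hair genes had 10 falls among 19, or 12 adjusted over the list alone (median -0.65, adjusted p = 8.38e-06, but adjusted p = 0.208 with an estimated correlation), with RHD2 at -2.31 ± 0.21 and LRX1 at -1.72 ± 0.21. Xylem markers had 4 falls among 8, or 6 adjusted over the list alone (median -0.80, adjusted p = 0.00268, but adjusted p = 0.182 with an estimated correlation), among them CESA4 (-1.25 ± 0.21). Ribosomal protein genes had 3 falls among 29, or 1 adjusted over the list alone (median -0.20, adjusted p = 0.00799, but adjusted p = 0.345 with an estimated correlation). Plastid genome genes had 20 falls among 132, and none adjusted over the list alone (median -0.27, adjusted p = 6.57e-10, but adjusted p = 0.276 with an estimated correlation). Mitochondrial genome genes had 12 falls among 129, and none adjusted over the list alone (median -0.18, adjusted p = 0.00219, but adjusted p = 0.473 with an estimated correlation), with ATMG00610 at -0.60 ± 0.14. When 2 h replicate 2 was left out, the falls numbered 67 among plastid, 30 (with 1 rise) among mitochondrial and 11 among ribosomal protein genes.

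At 12 h 11 lists were not called. Sucrose and raffinose family genes had 6 rises and 2 falls among 16, also adjusted over the list alone (adjusted p = 0.0813, called without 2 h replicate 2 at adjusted p = 0.0242). Gibberellin genes had 9 rises and 5 falls among 25, or 10 and 6 adjusted over the list alone (adjusted p = 0.0813). Small heat shock protein genes had 2 falls among 17, also adjusted over the list alone (adjusted p = 0.0678, called without 0 h replicate 2 at adjusted p = 0.0179). Antioxidant genes had 5 rises and 3 falls among 22, also adjusted over the list alone (adjusted p = 0.189). Cell cycle genes had 2 rises and 3 falls among 35, or 1 and 1 adjusted over the list alone (median 0.15, adjusted p = 0.696). Clock genes had 6 rises and 3 falls among 15, or 6 and 4 adjusted over the list alone (adjusted p = 0.339), with the morning gene LHY at -2.82 ± 0.73 and BOA at 2.76 ± 0.17. Dark- and starvation-induced genes had 1 rise and 2 falls among 8, also adjusted over the list alone (adjusted p = 0.531). Lipid mobilisation had 2 rises and 3 falls among 19, also adjusted over the list alone (adjusted p = 0.286). Seed oil synthesis had 1 rise and 2 falls among 12, also adjusted over the list alone (adjusted p = 0.82), with a median (0.13) and a mean (-0.02) of opposite sign. Endosperm and seed coat markers had 2 rises among 11, also adjusted over the list alone (adjusted p = 0.242). No root meristem marker of 5 was called, nor when adjusted over the list alone (adjusted p = 0.954, with camera pointing down and a median of 0.04). With 2 h replicate 2 left out there were 1 rise and 5 falls among small heat shock protein genes, 9 and 5 among antioxidant genes, 6 and 6 among cell cycle genes, 8 and 5 among clock genes and 2 and 7 in lipid mobilisation.

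The 12 h comparison called 7006 genes with limma, 3722 up and 3284 down. Of these 1334 rose and 1750 fell by at least 1. Without 2 h replicate 2, an array that enters only the estimate of spread here, 11351 genes were called, 5796 up and 5555 down. With each array centred the calls were 3163 up and 3583 down.

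The 24 h seeds against 0 h show the state after 1 day in ABA. LEA genes were up in 32 of 51 cases, and 15 of 35 cell cycle and 17 of 29 ribosomal protein genes were down. AT4G36600 rose by 7.70 ± 0.19 (adjusted p = 2.77e-12), AT4G39130 by 7.64, AT5G07330 by 7.48, AT2G42560 by 7.40 and RD29B by 7.38. EM1 rose by 6.68, EM6 by 5.34, RAB18 by 5.28, ABI5 by 4.11 and ABI3 by 1.79. The largest falls included ELIP2 (-7.20), ELIP1 (-6.98 ± 0.39), RBCS1B (-6.78, adjusted p = 1.06e-04), AT2G43140 (-6.28), AT1G29090 (-5.81 ± 0.61) and FTM1, an acyl carrier protein desaturase gene (-5.59 ± 0.13, adjusted p = 2.08e-12).

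LEA genes had 32 rises and 5 falls among 51 at 24 h, also adjusted over the list alone (median 3.21, adjusted p = 1.76e-16, but adjusted p = 0.122 with an estimated correlation). Storage and oil body genes reached their highest median, with 13 rises and no fall among 19, also adjusted over the list alone (4.42, adjusted p = 4.35e-09, but adjusted p = 0.258 with an estimated correlation). ABA receptor genes had 8 falls and 1 rise among 14, also adjusted over the list alone (median -0.95, adjusted p = 0.00113, but adjusted p = 0.0530 with an estimated correlation). Of the 9 PP2C genes 8 rose and 1 fell, also adjusted over the list alone (median 1.79, adjusted p = 1.31e-05, but adjusted p = 0.122 with an estimated correlation). ABA response markers had 11 rises and 4 falls among 24, or 13 and 4 adjusted over the list alone (median 0.71, adjusted p = 0.00113, but adjusted p = 0.18 with an estimated correlation), or 13 rises and 7 falls without 2 h replicate 2. Seed maturation and ABA transcription factors had 8 rises and no fall among 20, also adjusted over the list alone (median 0.54, adjusted p = 2.91e-04), with EEL up by 4.90 ± 0.22, FUS3 by 2.37 ± 0.28 and ABF1 by 1.99 ± 0.40. This list had 14 rises and 1 fall without 2 h replicate 2, and its call, which held with an estimated correlation (adjusted p = 0.0414), was lost with both together (adjusted p = 0.103). ABA synthesis and catabolism had 8 rises and 1 fall among 17, also adjusted over the list alone (median 0.35, adjusted p = 0.0191, but adjusted p = 0.149 with an estimated correlation).

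Cell cycle and DNA replication genes had 15 falls and 1 rise among 35, also adjusted over the list alone (median -0.37, adjusted p = 9.76e-04, but adjusted p = 0.373 with an estimated correlation). PCNA1, for the sliding clamp of DNA replication, changed by -1.95 ± 0.15 (adjusted p = 4.16e-07) and TSO2, for a ribonucleotide reductase subunit, by -1.39 ± 0.13. Ribosomal protein genes had 17 falls and 1 rise among 29, or 22 and 1 adjusted over the list alone (median -0.36, adjusted p = 3.57e-05, but adjusted p = 0.18 with an estimated correlation), with RPS21B at -1.07 ± 0.17. Expansin and xyloglucan transferase genes had 19 falls and 2 rises among 29, or 19 and 3 adjusted over the list alone (median -1.26, adjusted p = 1.31e-05, but adjusted p = 0.111 with an estimated correlation). Photosynthesis genes had 32 falls and no rise among 41, or 34 adjusted over the list alone (median -1.57, adjusted p = 1.57e-10, but adjusted p = 0.18 with an estimated correlation). Root hair genes had 10 falls among 19, or 12 adjusted over the list alone (median -0.68, adjusted p = 7.78e-04, but adjusted p = 0.36 with an estimated correlation). Lipid mobilisation had 6 falls and 2 rises among 19, or 8 and 2 adjusted over the list alone (median -0.33, adjusted p = 0.0293, but adjusted p = 0.48 with an estimated correlation). The citrate synthase gene CSY2 stood at -1.95 ± 0.33, while ACN1 rose by 2.24 ± 0.18. Mitochondrial genome genes had 42 falls and 3 rises among 129, also adjusted over the list alone (median -0.29, adjusted p = 2.19e-04, but adjusted p = 0.403 with an estimated correlation), with ATMG01020 at -1.51 ± 0.33. Mitochondrial genes had 61 falls and 8 rises without 2 h replicate 2, and lipid mobilisation 11 falls and 2 rises.

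Clock genes had 8 rises and 3 falls among 15 at 24 h, or 9 and 3 adjusted over the list alone (median 1.14, adjusted p = 0.0353, but adjusted p = 0.232 with an estimated correlation). FKF1 and PRR5, which peak late in the day, rose by 2.81 ± 0.35 and 2.63 ± 0.28, and LHY stood at -3.43 ± 0.73. The clock call was lost without 0 h replicate 2 (adjusted p = 0.0564) and with each array centred (adjusted p = 0.0567).

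The lists not called at 24 h numbered 10. Sucrose and raffinose family genes had 8 rises and 4 falls among 16, or 9 and 4 adjusted over the list alone (adjusted p = 0.0692, called without 2 h replicate 2 at adjusted p = 0.0238), with SUS3 up by 5.36 ± 0.28 and DIN10 at -5.24 ± 0.19. Gibberellin genes had 11 rises and 6 falls among 25, also adjusted over the list alone (adjusted p = 0.227). Antioxidant genes had 7 rises and 5 falls among 22, or 7 and 6 adjusted over the list alone (adjusted p = 0.426), and small heat shock protein genes 1 rise and 3 falls among 17, also adjusted over the list alone (adjusted p = 0.314). Plastid genome genes had 1 rise and 21 falls among 132, or 16 falls adjusted over the list alone (adjusted p = 0.218). Dark- and starvation-induced genes had 3 rises and 2 falls among 8 (adjusted p = 0.979), seed oil synthesis 4 and 4 among 12 (adjusted p = 0.894), and both counts were unchanged adjusted over the list alone. Xylem markers had 2 falls among 8 (adjusted p = 0.23), endosperm and seed coat markers 1 rise among 11 (adjusted p = 0.392) and root meristem markers no call among 5 (adjusted p = 0.894), again with equal counts adjusted over the list alone. With 2 h replicate 2 left out there were 2 rises and 5 falls among small heat shock protein genes, 6 and 25 among plastid genes, 1 and 4 among xylem markers, 2 rises among endosperm and seed coat markers and 1 among root meristem markers.

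At 24 h 10230 genes were called by limma, 4878 up and 5352 down. Changes of at least 1 numbered 2099 up and 2698 down.

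The 72 h seeds, against 0 h, show the end of the course. LEA genes were up in 30 of 51 cases, and 25 of 35 cell cycle, 19 of 29 ribosomal protein and 30 of 41 photosynthesis genes were down. AT5G07330 rose by 7.49 ± 0.21, AT4G36600 by 7.43, RD29B by 7.33 ± 0.20, EM1 by 6.43 and EM6 by 5.40. RAB18 rose by 5.30, from 6.24 to 11.54, ABI5 by 4.03 and ABI3 by 1.65. The largest falls were in ELIP2 (-7.03 ± 0.95), RBCS1B (-6.42, adjusted p = 1.47e-04), AT1G29090 (-6.00 ± 0.61), the cutinase gene CDEF1 (-5.89 ± 0.56), the haemoglobin gene HB1 (-5.87 ± 0.33), AT2G27420 (-5.77), AT2G43150 (-5.76 ± 0.78) and FTM1 (-5.70 ± 0.13).

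LEA genes had 30 rises and 6 falls among 51 at 72 h, also adjusted over the list alone (median 2.64, adjusted p = 3.13e-14, but adjusted p = 0.104 with an estimated correlation). Storage and oil body genes had 10 rises and no fall among 19, also adjusted over the list alone (median 2.74, adjusted p = 2.53e-05, but adjusted p = 0.394 with an estimated correlation). Seed maturation and ABA transcription factors had 10 rises and no fall among 20, or 12 adjusted over the list alone (median 0.98, adjusted p = 1.33e-05), a call that held with an estimated correlation (adjusted p = 0.0125) but not with that and 2 h replicate 2 left out together (adjusted p = 0.113). EEL rose by 4.79, ABF3 by 2.67 ± 0.43 and ABF1 by 2.61 ± 0.40. ABA receptor genes had 8 falls and 2 rises among 14, also adjusted over the list alone (median -0.64, adjusted p = 0.00793, but adjusted p = 0.0748 with an estimated correlation). ABA response markers had 12 rises and 2 falls among 24, also adjusted over the list alone (median 0.86, adjusted p = 3.11e-04, but adjusted p = 0.121 with an estimated correlation). ABA synthesis and catabolism had 8 rises among 17, or 9 rises and 1 fall adjusted over the list alone (median 0.60, adjusted p = 0.00554, but adjusted p = 0.0748 with an estimated correlation), with CYP707A2 up by 3.49 ± 0.21 and NCED2 by 1.94 ± 0.23. Storage genes without 2 h replicate 2 had 12 rises and 2 falls, and ABA response markers 12 and 4.

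Of the 9 clade A PP2C genes, 8 rose at 72 h with no fall, also adjusted over the list alone (median 1.93, adjusted p = 8.69e-07, but adjusted p = 0.0748 with an estimated correlation). AHG1 rose (adjusted p = 6.82e-10), as did HAI3 by 4.29 ± 0.22, HAI2 by 4.13 ± 0.31, ABI2 by 2.78 ± 0.25, PP2CA by 1.93 ± 0.17, HAB1 by 1.54 ± 0.39 and HAB2 by 1.12 ± 0.23. HAI1 rose by 0.62 ± 0.20 (adjusted p = 0.0268), a call lost without 0 h replicate 1 (0.0527), 0 h replicate 2 (0.0543), 0 h replicate 3 (0.0899) or 72 h replicate 2 (0.144, with a change of 0.40). ABI1 did not pass the test (0.30 ± 0.17, adjusted p = 0.204). Dark- and starvation-induced genes had 1 rise and 3 falls among 8, also adjusted over the list alone, and were not called (adjusted p = 0.528, 3 rises and 4 falls without 2 h replicate 2). DIN10 stood at -4.62 ± 0.19 (adjusted p = 7.17e-10) and DIN9 at -1.08 ± 0.23 (adjusted p = 0.00159), and the dormancy-associated gene DRM1 rose by 1.82 ± 0.13. DIN4 stood at -0.75 (adjusted p = 0.0325), a call lost without 0 h replicate 1 (0.0783), replicate 2 (0.0628) or replicate 3 (0.0850), or without 72 h replicate 1 (0.118) or replicate 3 (0.0696). ASN1 (0.99 ± 0.79), SEN1 (0.23), DIN2 (0.65) and DIN11 (-0.43) did not pass the test.

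Cell cycle and DNA replication genes had 25 falls and no rise among 35 at 72 h, or 25 falls and 1 rise adjusted over the list alone (median -0.91, adjusted p = 1.11e-07, but adjusted p = 0.147 with an estimated correlation). PCNA1 changed by -2.95 ± 0.15 (adjusted p = 6.65e-09), PCNA2 by -1.95 ± 0.23 and the replication helicase gene MCM3 by -1.89 ± 0.22. Ribosomal protein genes had 19 falls among 29, or 19 falls and 1 rise adjusted over the list alone (median -0.53, adjusted p = 1.82e-05, but adjusted p = 0.147 with an estimated correlation). Expansin and xyloglucan transferase genes had 19 falls and 5 rises among 29, or 21 and 5 adjusted over the list alone (median -1.33, adjusted p = 1.32e-05, but adjusted p = 0.0748 with an estimated correlation). XTH18 changed by -5.02 ± 0.31 and XTH24 by -4.12 ± 0.37. Photosynthesis genes had 30 falls and no rise among 41, or 32 adjusted over the list alone (median -1.54, adjusted p = 7.39e-09, but adjusted p = 0.198 with an estimated correlation), with LHCB1.2 at -3.63 ± 0.48 and the plastocyanin gene PETE1 at -3.22 ± 0.47. Lipid mobilisation had 9 falls and 1 rise among 19, or 9 and 2 adjusted over the list alone (median -0.37, adjusted p = 0.00793, but adjusted p = 0.394 with an estimated correlation). Mitochondrial genome genes had 67 falls and 3 rises among 129, or 68 and 3 adjusted over the list alone (median -0.73, adjusted p = 4.44e-08, but adjusted p = 0.208 with an estimated correlation), with ATMG01020 at -2.39 ± 0.33 and ATMG01090 at -2.16 ± 0.15. Plastid genome genes moved the other way, with 33 rises and 13 falls among 132, also adjusted over the list alone (median 0.18, adjusted p = 0.00793, but adjusted p = 0.675 with an estimated correlation). The list's call was lost on repeating quantile normalization (median 0.06, adjusted p = 0.320). With 2 h replicate 2 left out there were 51 rises and 16 falls among plastid, 7 and 78 among mitochondrial and 2 and 27 among cell cycle genes.

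Clock genes had 11 rises and 3 falls among 15 at 72 h, also adjusted over the list alone (median 2.13, adjusted p = 2.11e-04, but adjusted p = 0.0748 with an estimated correlation). PRR9 rose by 4.02 ± 0.45, PRR5 by 3.94 ± 0.28 and FKF1 by 3.57 ± 0.35, while LHY stood at -3.47 ± 0.73. All arrays were taken at 5 fixed incubation times, and the time of day of each harvest is not given in the sources used here.

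**Figure D4:**
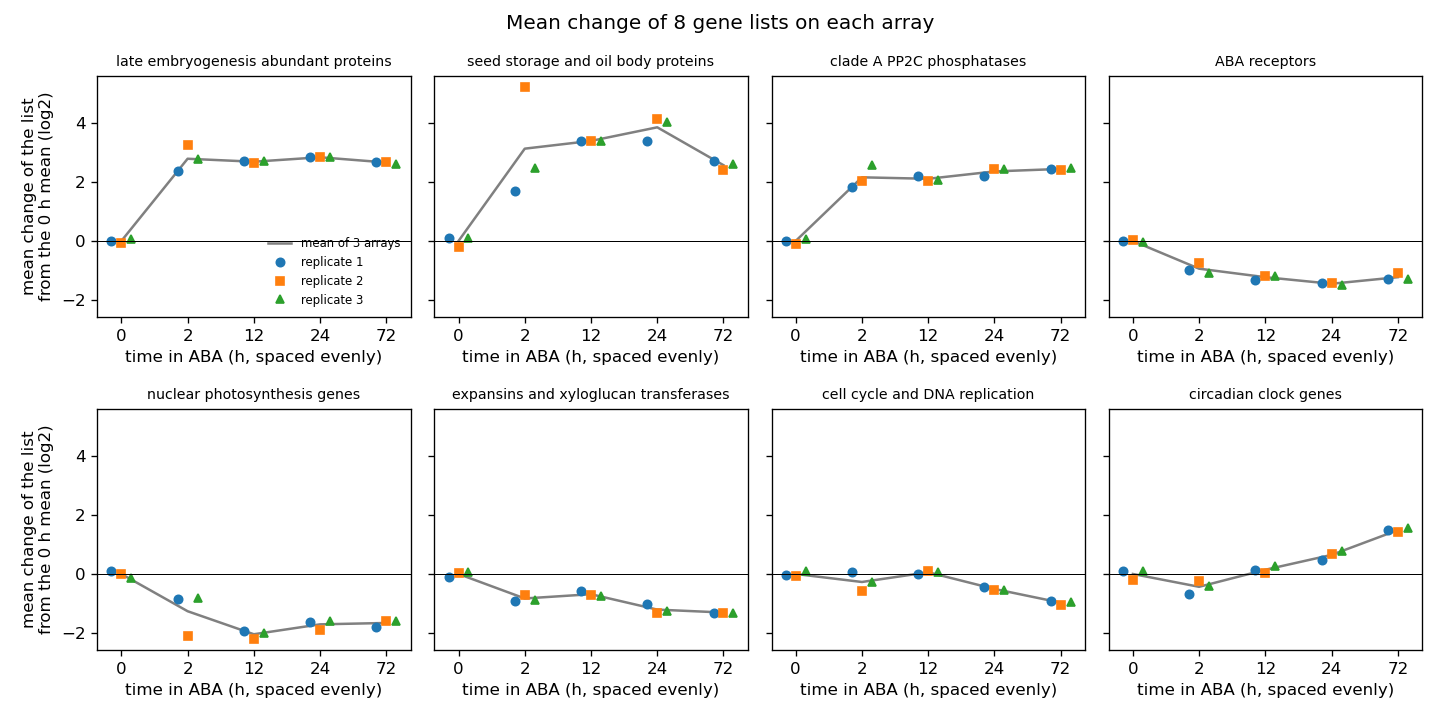
Mean change of 8 gene lists from their 0 h mean (log2) on each array by time in ABA, with 1 symbol per replicate and a line through the mean of 3 arrays. LEA, storage and PP2C genes lie above 0 on every array after 0 h, and photosynthesis, ABA receptor and expansin genes below 0.

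The 9 lists not yet described were not called at 72 h. Gibberellin genes had 9 rises and 5 falls among 25, or 10 and 5 adjusted over the list alone (adjusted p = 0.154). Sucrose and raffinose family genes had 8 rises and 2 falls among 16, or 9 and 2 adjusted over the list alone (adjusted p = 0.0677). They were called without 2 h replicate 1 (adjusted p = 0.0485) or 2 h replicate 2 (adjusted p = 0.0211). Small heat shock protein genes had 2 rises and 4 falls among 17 (adjusted p = 0.528). Antioxidant genes had 5 rises and 7 falls among 22 (adjusted p = 0.84, median -0.08, mean 0.17). Seed oil synthesis had 3 rises and 4 falls among 12 (adjusted p = 0.84, median 0.06, mean -0.05). Root hair genes had 1 rise and 5 falls among 19 (adjusted p = 0.154). In these 4 lists the counts were equal adjusted over the list alone. Xylem markers had 2 falls among 8 (adjusted p = 0.231) and root meristem markers no call among 5 (adjusted p = 0.644), also adjusted over the list alone. Endosperm and seed coat markers had 2 rises among 11, or 1 adjusted over the list alone (adjusted p = 0.528). With 2 h replicate 2 left out there were 3 rises and 7 falls among small heat shock protein genes, 1 and 8 among root hair genes and 1 and 3 among xylem markers.

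At 72 h limma called 10777 genes, 5137 up and 5640 down. The rises and falls of at least 1 numbered 2384 and 2893.

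The steps between successive times ask when changes took place. From 2 h to 12 h, 5 of 24 ABA response markers and 9 of 41 photosynthesis genes fell. ELIP1 changed by -4.17 ± 0.39 (adjusted p = 2.16e-04) and RD26, a stress-induced NAC gene, by -2.65 ± 0.49 (adjusted p = 0.00917), while AT4G35720 rose by 2.90 ± 0.36 and AT2G39430 by 2.53 ± 0.21 (adjusted p = 1.11e-04). ABA response markers had 5 falls among 24, or 11 adjusted over the list alone (median -0.67, adjusted p = 7.18e-04, but adjusted p = 0.461 with an estimated correlation). That call was lost without 2 h replicate 3 (median -0.39, adjusted p = 0.104). Photosynthesis genes had 9 falls among 41, or 13 adjusted over the list alone (median -0.77, adjusted p = 4.85e-06, but adjusted p = 0.576 with an estimated correlation), and their median was -0.47 without 2 h replicate 1. Clock genes had 6 rises and 1 fall among 15, or 8 and 1 adjusted over the list alone (median 0.65, adjusted p = 0.00394, but adjusted p = 0.461 with an estimated correlation). Plastid genome genes had 2 falls among 132, and none adjusted over the list alone (median -0.17, adjusted p = 4.64e-05, but adjusted p = 0.576 with an estimated correlation). Mitochondrial genome genes had 8 falls among 129, or 9 adjusted over the list alone (median -0.15, adjusted p = 0.00394, but adjusted p = 0.598 with an estimated correlation). The mitochondrial call was lost without 12 h replicate 1 (median -0.07, adjusted p = 0.0994), 2 h replicate 1 (-0.09, 0.316) or 2 h replicate 3 (0.110), and the median was -0.24 without 2 h replicate 2. Leaving out that array gave 14 falls among ABA response markers, 31 among photosynthesis genes, 18 among plastid genes and 18 among mitochondrial genes.

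A further 3 lists rested on the 2 h replicate 2 array in this step. Cell cycle genes had 5 rises among 35, or 6 adjusted over the list alone (median 0.33, adjusted p = 1.17e-04, but adjusted p = 0.576 with an estimated correlation), and were not called without 2 h replicate 2 (6 rises and 2 falls, median 0.17, adjusted p = 0.0546). Small heat shock protein genes had 2 falls among 17, or 5 adjusted over the list alone (median -0.88, adjusted p = 8.82e-04, but adjusted p = 0.576 with an estimated correlation), and were not called without it (median -0.22, adjusted p = 0.152). No root hair gene of 19 was called, nor when adjusted over the list alone, and the list was shifted down (median -0.36, adjusted p = 0.0083, but adjusted p = 0.576 with an estimated correlation). This was lost without 2 h replicate 2 (median -0.11, adjusted p = 0.257) and on repeating quantile normalization (adjusted p = 0.296), and the median was -0.57 without 2 h replicate 3. Without 2 h replicate 2, storage and oil body genes were shifted up (median 1.60, adjusted p = 3.77e-11), as were expansin and xyloglucan transferase genes (median 0.11, adjusted p = 0.0307), while ribosomal protein genes (median -0.13, adjusted p = 0.00678) and lipid mobilisation (median -0.22, adjusted p = 0.0078) were shifted down. With all arrays these 4 lists were not called (adjusted p = 0.101, 0.0859, 0.298 and 0.768). With that array left out and an estimated correlation, 0 lists were called in this step. Centring each array also called storage (adjusted p = 0.0197) and ribosomal protein genes (adjusted p = 0.0278), and antioxidant genes were called without 2 h replicate 3 (adjusted p = 0.0234). LEA genes were not called (median -0.03, adjusted p = 0.837).

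From 2 h to 12 h limma called 1369 genes, 916 up and 453 down, with 276 rises and 171 falls of at least 1. The count was 2146, 4276 and 4765 without 2 h replicate 1, 2 and 3, and 380, 659 and 385 without 12 h replicate 1, 2 and 3. Rises and falls of at least 1 numbered 432 and 344 without 2 h replicate 1, 489 and 424 without 2 h replicate 2, 666 and 642 without 2 h replicate 3, 125 and 97 without 12 h replicate 1, 152 and 87 without 12 h replicate 3, and 131 and 301 with each array centred. With each array centred it was 376 up and 723 down, so which direction held more calls depended on the scaling.

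From 12 h to 24 h, 2 of 15 clock genes rose, and 8 of 35 cell cycle and 7 of 29 expansin and xyloglucan transferase genes fell. TCH3 rose by 3.70 ± 0.54, CYP71A13, a cytochrome P450 gene of camalexin synthesis, by 3.61 ± 0.49 (adjusted p = 0.00109), the glutathione transferase gene GSTU12 by 3.58 ± 0.36, GRP3S by 3.57 ± 0.44 and AT1G26380 by 3.50 ± 0.34. FTM1 changed by -4.19 ± 0.13 (adjusted p = 4.28e-10), HB1 by -3.71 ± 0.33 and GASA6, of a gibberellin-regulated family, by -3.58 ± 0.27. Cell cycle genes had 8 falls among 35, or 15 adjusted over the list alone (median -0.54, adjusted p = 9.05e-12, but adjusted p = 0.156 with an estimated correlation). Expansin and xyloglucan transferase genes had 7 falls and 1 rise among 29, or 9 and 2 adjusted over the list alone (median -0.33, adjusted p = 1.21e-04, but adjusted p = 0.156 with an estimated correlation), with a median of -0.59 without 24 h replicate 1. Ribosomal protein genes had 2 falls among 29, or 4 adjusted over the list alone (median -0.22, adjusted p = 1.21e-04, but adjusted p = 0.359 with an estimated correlation). Seed maturation and ABA transcription factors had 1 rise among 20, also adjusted over the list alone (median 0.31, adjusted p = 0.00865, but adjusted p = 0.156 with an estimated correlation). Clock genes had 2 rises among 15, or 4 adjusted over the list alone (median 0.65, adjusted p = 0.00453, but adjusted p = 0.156 with an estimated correlation). Plastid genome genes had 6 rises and 1 fall among 132, or 17 and 1 adjusted over the list alone (median 0.21, adjusted p = 2.2e-09, but adjusted p = 0.569 with an estimated correlation). When 2 h replicate 2 was left out, the falls numbered 24 among cell cycle, 11 (with 3 rises) among expansin and 8 among ribosomal protein genes, and the rises 8 (with 1 fall) among the transcription factors, 7 among clock genes and 36 (with 4 falls) among plastid genes.

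The other called lists of this step each lost their call without a single array. Photosynthesis genes had 4 rises and 1 fall among 41, or 6 and 1 adjusted over the list alone (median 0.36, adjusted p = 0.00453, adjusted p = 0.78 with an estimated correlation, 0.0539 without 12 h replicate 2). Xylem markers had 1 rise among 8, or 2 adjusted over the list alone (median 0.36, adjusted p = 0.0186, adjusted p = 0.437 with an estimated correlation), and were not called without 12 h replicate 1 (median 0.19, adjusted p = 0.0583) or 24 h replicate 1 (adjusted p = 0.0571). Mitochondrial genome genes had 18 falls and 2 rises among 129, or 22 and 4 adjusted over the list alone (median -0.18, adjusted p = 0.00865, adjusted p = 0.78 with an estimated correlation). Their call was lost without 12 h replicate 2 (median -0.10, adjusted p = 0.103) or 24 h replicate 1 (-0.10, 0.0571). Lipid mobilisation had 1 rise among 19, or 1 rise and 3 falls adjusted over the list alone (median -0.24, adjusted p = 0.0351, adjusted p = 0.78 with an estimated correlation). This was lost without 12 h replicate 2 (adjusted p = 0.0987), 12 h replicate 3 (0.0523), 2 h replicate 1 (0.0516) or 24 h replicate 1 (0.0571) and with each array centred (0.0519). Without 2 h replicate 2, LEA genes (median 0.14, adjusted p = 0.0274) and storage genes (median 0.53, adjusted p = 0.0118) were called up, which they were not with all arrays (adjusted p = 0.0947 and 0.19), and there were 18 rises and 7 falls among photosynthesis genes, 8 and 38 among mitochondrial genes, 2 and 7 in lipid mobilisation and 2 rises among xylem markers.

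For the step from 12 h to 24 h limma called 1835 genes, 770 up and 1065 down, with 251 rises and 325 falls of at least 1. The count was 863, 723 and 825 without 12 h replicate 1, 2 and 3, 655 and 730 without 24 h replicate 2 and 3, and 5973 without 2 h replicate 2. Those of at least 1 were 165 rises and 212 falls without 24 h replicate 2, and 147 rises without 12 h replicate 2. With each array centred the calls were 903 up and 756 down, and with quantile normalization repeated 1036 up and 1152 down.

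From 24 h to 72 h, 5 of 15 clock genes rose, while 2 of 19 storage and 6 of 35 cell cycle genes fell. ELIP1 rose by 5.43 ± 0.39 (adjusted p = 4.02e-06), the myrosinase genes BGLU35 and BGLU34 by 4.61 ± 0.46 and 4.29 ± 0.30 and the locus AT3G51238 by 4.24 ± 0.41, and F3H, a flavonoid synthesis gene next to it, also rose (adjusted p = 2.83e-04). The lectin gene AT3G16530 changed by -3.58 ± 0.51, AT2G15220 by -3.45 ± 0.50, CYP71A13 by -3.43 ± 0.49 and CYP82C2 by -3.37 ± 0.20 (adjusted p = 1.46e-06). Storage and oil body genes had 2 falls among 19, or 7 adjusted over the list alone (median -1.20, adjusted p = 2.92e-06, but adjusted p = 0.49 with an estimated correlation). Cell cycle genes had 6 falls among 35, or 18 adjusted over the list alone (median -0.53, adjusted p = 1.12e-11, but adjusted p = 0.226 with an estimated correlation). Mitochondrial genome genes had 13 falls and 1 rise among 129, or 38 and 3 adjusted over the list alone (median -0.29, adjusted p = 2.35e-09, but adjusted p = 0.28 with an estimated correlation). Antioxidant genes had 3 falls among 22, or 4 falls and 1 rise adjusted over the list alone (median -0.18, adjusted p = 0.0159, but adjusted p = 0.26 with an estimated correlation). Clock genes had 5 rises among 15, or 7 adjusted over the list alone (median 0.76, adjusted p = 1.65e-08), a call that held with an estimated correlation (adjusted p = 0.0181) but not with that and 2 h replicate 2 left out together (adjusted p = 0.219). Plastid genome genes had 6 rises among 132, or 7 adjusted over the list alone (median 0.21, adjusted p = 3.34e-17, but adjusted p = 0.26 with an estimated correlation). Root hair genes had 3 rises among 19, or 5 adjusted over the list alone (median 0.13, adjusted p = 1.97e-04, but adjusted p = 0.4 with an estimated correlation), with medians of 0.23 without 24 h replicate 1, 0.04 without 72 h replicate 2 and 0.20 without 72 h replicate 3. When 2 h replicate 2 was left out, the falls numbered 12 among storage, 22 among cell cycle, 57 (with 2 rises) among mitochondrial and 6 (with 2 rises) among antioxidant genes, and the rises 8 among clock, 35 among plastid and 5 among root hair genes.

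LEA genes were not called from 24 h to 72 h (median -0.12, adjusted p = 0.0761), nor were ABA receptor genes (adjusted p = 0.0674) or seed maturation and ABA transcription factors (adjusted p = 0.0738). LEA genes were called without 2 h replicate 1 (adjusted p = 0.0368) and with quantile normalization repeated (adjusted p = 0.0246), which also called lipid mobilisation (adjusted p = 0.0421). The receptor list was called without 2 h replicate 1 (adjusted p = 0.0402), 24 h replicate 2 (0.0407), 72 h replicate 1 (0.0461) or 72 h replicate 3 (0.0327), the transcription factor list without 24 h replicate 2 (0.0482) or 72 h replicate 3 (0.0441), and both with each array centred (0.0487). From 24 h to 72 h limma called 928 genes, 540 up and 388 down, with 301 rises and 169 falls of at least 1. That count was 413 and 418 without 24 h replicate 2 and 3, 488, 460 and 407 without 72 h replicate 1, 2 and 3, and 3588 without 2 h replicate 2. Falls of at least 1 were 295 without 2 h replicate 2, 102 (with 196 rises) without 24 h replicate 2, 109 without 24 h replicate 3 and 105 (with 192 rises) without 72 h replicate 3.

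Among the lists not called in these steps, the signs of median, mean and camera differed in some cases. From 2 h to 12 h these were the PP2C genes, the seed maturation transcription factors, the gibberellin genes and the root meristem markers, and from 12 h to 24 h the gibberellin, antioxidant and endosperm lists. From 24 h to 72 h they were the gibberellin, small heat shock protein, photosynthesis, seed oil and xylem lists.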

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

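The test of a swap of the 2 h replicate 2 array with another time was chosen only after the result was seen, and the choice of the genes and the list below, which differ between times, followed a rule fixed earlier.

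Against 0 h, 249 genes were called in opposite directions at 2 times, and the 4 with the largest difference between these times are given here because that difference was itself tested with limma. AT2G25450, a dioxygenase gene of glucosinolate metabolism, was at -2.32 at 12 h and 2.42 at 72 h, a difference of 4.74 ± 0.40 (adjusted p = 5.32e-06). AT1G18330, a MYB-like gene of the clock family, was at -2.13 at 2 h and 2.44 at 72 h, a difference of 4.58 ± 0.28 (adjusted p = 2.94e-07). The flavonoid synthesis gene F3H was at -2.85 at 12 h and 1.29 at 72 h, a difference of 4.15 ± 0.48 (adjusted p = 5.72e-05). AT3G51238, annotated as a noncoding RNA next to F3H, was at -3.05 at 12 h and 1.36 at 72 h, a difference of 4.41 ± 0.41 (adjusted p = 1.21e-05). These neighbours are not independent of each other if signal is shared between them, which was not tested. The 72 h rise of AT3G51238 was not called without 0 h replicate 2 (adjusted p = 0.0537), 0 h replicate 3 (0.0623) or 72 h replicate 3 (0.0605). The 72 h rise of F3H was not called without 0 h replicate 1 (0.0533), 2 (0.119) or 3 (0.125), 12 h replicate 1 (0.0572), 2 (0.0574) or 3 (0.0588), 24 h replicate 1 (0.0587), 2 (0.0568) or 3 (0.0578), 72 h replicate 1 (0.107), 2 (0.0755) or 3 (0.111), or with quantile normalization repeated (0.0868). The differences between the times passed the test in all of these.

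Plastid genome genes were also shifted in opposite directions. Their median difference was 0.26 between 72 h and 2 h (adjusted p = 8.14e-08, and adjusted p = 0.703 with an estimated correlation) and 0.42 between 72 h and 12 h (adjusted p = 6.59e-20, and adjusted p = 0.272 with an estimated correlation). The shift at 2 h against 0 h turned to 0.03 with each array centred.

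The 2 h replicate 2 array stood apart from every other array. Its highest correlation was 0.911 with another time and 0.901 with its replicates, below the 0.986 elsewhere. If poor, it can give this swapped or not, so a swap is undecided. Among genes above the median level it correlated at 0.830 with the mean of its replicates, which correlated at 0.959 with each other, so a raised background that moves only dim probe sets is not the whole cause. Its deviation shared a squared correlation of at most 0.139 with the changes along the course, which argues against seeds of an earlier or later stage as the whole cause. The deviation correlated at -0.525 with the level in its replicates, as a compressed signal would give, but noise in those replicates pulls that value below 0 too. Poor RNA or hybridization or a sample from outside this series may remain, and no value here decides between them. Beyond seed stage no biological explanation was tested.

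Other splits were counted. Over the course, 1 of 100 splits into 5 groups of 3, the real one, gave as many genes. It had 12302 against at most 918 elsewhere, so chance is unlikely, but handling differences were not tested. For each comparison of 3 arrays with 3, 10 splits are too few for a share under 0.05. The real counts were 4433, 7006, 10230 and 10777 at 2, 12, 24 and 72 h against 0 h, with 1 gene in the highest other split at 2 h and 0 at the later times, and 1369, 1835 and 928 in the successive steps, with 0 genes in the highest other split, by limma at adjusted p under 0.05.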

How the results depend on the processing

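The estimated inter-gene correlation with 2 h replicate 2 left out was chosen after seeing the data, and the other tests of this part were planned. No call of a named gene reversed in the alternatives that tested single genes, and 1 list reversed, the plastid genome genes at 2 h, whose median was 0.025 with each array centred and whose cause is that centring adds 0.12 to every change at 2 h. With an estimated inter-gene correlation 9 of the 84 list calls remained in number, 5 at 2 h, 1 each at 12, 24 and 72 h, 0 from 2 h to 12 h, 0 from 12 h to 24 h and 1 from 24 h to 72 h, and with 2 h replicate 2 left out as well 3 did, all at 2 h, with 0 in each other comparison. With fry, which asks another question, 95 lists were called. Adjusted p under 0.01 left 2542 genes at 2 h, 4514 at 12 h, 309 from 2 h to 12 h, 600 from 12 h to 24 h and 373 from 24 h to 72 h, by construction fewer. Array weights, which put 2 h replicate 2 at 0.0408 against at least 0.522 for the others, gave 13288 genes at 12 h, 15458 at 24 h, 3301 from 2 h to 12 h, 9337 from 12 h to 24 h and 5717 from 24 h to 72 h. Fits of only the 6 arrays compared gave 1276 at 2 h, 11400 at 12 h, 5605 from 12 h to 24 h, 3184 from 24 h to 72 h and 0 from 2 h to 12 h by limma, where 2749 genes had an unadjusted p under 0.05 against 7862 with all arrays. The cause of these moves was not tested beyond leaving out arrays. The number of genes highest at 2 h was 903 with each array centred, the cause of which was not tested, and a range of at least 2 left, by construction, 939, 94, 119, 344 and 393 genes highest at 0, 2, 12, 24 and 72 h. Leaving out each array in turn gave 10652 to 16423 genes over the course, 2992 to 7086 at 2 h, 5316 to 11351 at 12 h, 8436 to 13741 at 24 h, 9181 to 14318 at 72 h, 380 to 4765 from 2 h to 12 h, 655 to 5973 from 12 h to 24 h and 407 to 3588 from 24 h to 72 h. The highest value came without 2 h replicate 2 in all of these except 2 h (without 2 h replicate 1) and 2 h to 12 h (without 2 h replicate 3). The genes highest at 0, 2, 12, 24 and 72 h ranged over 2910 to 3461, 477 to 1020, 503 to 634, 861 to 1272 and 1789 to 2134. List calls ranged over 82 to 89 in all, 14 to 17 at 2 h, 14 to 15 at 12 h, 14 to 16 at 24 h, 15 to 16 at 72 h, 7 to 9 from 2 h to 12 h, 7 to 12 from 12 h to 24 h and 7 to 9 from 24 h to 72 h. A replicate term gave 4417 genes at 2 h and 10654 at 72 h. The labels give no pairing, so none was assumed. With time means removed, 11 of 30 pairs of equal number correlated above 0.1, none with 24 h. The median was 0.0455 in the 30 and -0.0192 in other pairs, and 8 of 15 arrays correlated best with their own number. A source shared by the other times is open. Among named genes 257 calls were lost over the 14 arrays other than 2 h replicate 2 left out in turn, 2 without that array, 10 with centring, 11 with quantile normalization, 5 with the replicate term, 2 with the intensity trend and 1 with array weights. With few arrays and RMA values, changes in dim genes are limited by signal over background, and leaving out the 25% of genes with the lowest mean gave 81 list calls.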

Other observations

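The gene lists of this part and the test of clock phase were chosen only after the data had been seen, so what the lists show is a hypothesis on the arrays that gave it, and their p-values are adjusted over the 7 lists.

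Genes induced by low oxygen fell late in the course. Of 14 core hypoxia-responsive genes, 12 fell and 1 rose at 24 h against 0 h (median -1.64, adjusted p = 4.99e-06, but adjusted p = 0.19 with an estimated correlation) and 11 fell and 1 rose at 72 h (median -1.95, adjusted p = 1.38e-05, but adjusted p = 0.148 with an estimated correlation). At 72 h PDC1, for pyruvate decarboxylase, stood at -4.23, ACO1 at -3.62, the sucrose synthase gene SUS4 at -3.47 and the alcohol dehydrogenase gene ADH1 at -2.60, while HUP7 rose by 2.41. Most of the fall lay between 12 h and 24 h, with 8 falls (median -1.47, adjusted p = 1.82e-11). The list was not called at 2 h (3 rises, 3 falls, adjusted p = 0.608) or 12 h (2 rises, 5 falls, adjusted p = 0.217).

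Indolic phytoalexin genes, which make defence compounds from tryptophan, were as a list higher at 24 h than at 12 h or 72 h, and were not called at 24 h against 0 h (5 rises, 1 fall, median 0.70, adjusted p = 0.0511). They were called there without 0 h replicate 1 (adjusted p = 0.0356), 2 h replicate 1 (0.0450), 2 (0.0246) or 3 (0.0338), 12 h replicate 2 (0.0483), 24 h replicate 3 (0.0375) or 72 h replicate 2 (0.0495), or with quantile normalization repeated (0.0486), but not with an estimated correlation (adjusted p = 0.286). Against 0 h the list was lower at 2 h (3 fell, median -0.44, adjusted p = 0.00455, but adjusted p = 0.185 with an estimated correlation) and 72 h (5 fell, 1 rose, median -0.77, adjusted p = 0.0168, but adjusted p = 0.169 with an estimated correlation), and not called at 12 h (adjusted p = 0.142). Of 12 genes 5 rose and none fell from 12 h to 24 h (median 0.83, adjusted p = 5.99e-07), and 7 fell and none rose from 24 h to 72 h (median -1.37, adjusted p = 8.01e-18). The regulator gene MYB51 rose by 2.66 ± 0.15 and then stood at -2.18, and CYP71A12 rose by 1.82 and then stood at -1.37. Immune elicitor-induced genes were lower than at 0 h at 2 h (6 of 14 fell, median -0.69, adjusted p = 2.77e-04, but adjusted p = 0.148 with an estimated correlation), at 12 h (7 fell, median -1.17, adjusted p = 3.77e-06, but adjusted p = 0.0577 with an estimated correlation), and at 72 h (6 fell, 1 rose, median -0.60, adjusted p = 0.00408, but adjusted p = 0.16 with an estimated correlation), and were not called at 24 h (4 rises, 6 falls, median -0.33, adjusted p = 0.275). In the same list 5 genes rose and none fell from 12 h to 24 h, and 5 fell and 1 rose from 24 h to 72 h (median -0.37, adjusted p = 1.31e-04, but adjusted p = 0.0728 with an estimated correlation). In the phytoalexin list mean the lowest 24 h array lay 0.834 above the highest 12 h or 72 h array. No single array made this gap, but choosing lists from these data favours gaps. Microbial growth in the dishes at 24 h may be a candidate explanation and cannot be told apart from a response of the seeds, because the median rise of the immune list, 0.471, lay just under the bound of 0.5 set for it although the list was called (adjusted p = 1.71e-07), and no sterile control was analysed here.

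Light-induced genes fell early and partly came back. Of 18 genes 13 fell and 1 rose at 2 h (median -1.54, adjusted p = 4.2e-09), 16 fell and 1 rose at 12 h (median -2.16, adjusted p = 1.63e-10), 17 fell and 1 rose at 24 h (median -2.09, adjusted p = 1.1e-08) and 12 fell and 3 rose at 72 h (median -1.03, adjusted p = 0.00383, but adjusted p = 0.143 with an estimated correlation). From 24 h to 72 h 8 rose and none fell (adjusted p = 7.92e-11), among them HY5, a master regulator of light responses, by 3.09 ± 0.27, BIC2 by 2.18 and GNC by 1.61. The lowest 72 h array lay 0.728 above the highest 24 h array in the list mean, a gap list choice favours. Light before the 72 h harvest may be the source and cannot be told apart from other sources, because the light-induced median of 0.594 is what it needs but the 8 dark-expressed genes had 1 rise and no fall (median -0.08, mean 0.17, adjusted p = 0.935), where a fall was needed, and at 72 h against 0 h 4 rises and 1 fall (adjusted p = 0.11). A shift of clock phase cannot be told apart either, with a median change of morning genes minus evening genes of -0.682. In this step 2 of 5 morning genes rose (median 0.31, adjusted p = 0.00542, but adjusted p = 0.0822 with an estimated correlation), with medians of 0.03 without 24 h replicate 1 (adjusted p = 0.162), 0.05 without 72 h replicate 3, 0.50 without 24 h replicate 3 and 0.48 without 72 h replicate 2. Evening clock genes had 3 rises among 8 from 24 h to 72 h (median 0.99, adjusted p = 1.25e-07).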
